A study of Mus musculus with 20 samples.

How the data were processed

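Gene expression had been measured on Affymetrix Mouse430_2 arrays in 10 blood cell types of wild-type C57Bl/6 mice, which the labels give as female and 12 to 14 weeks old. Per the labels, between 25000 and 50000 cells were sorted by flow cytometry for a sample, RNA was extracted with a commercial kit, treated with DNase and amplified linearly by in vitro transcription, and the labelled product was biotinylated. Each of the 20 arrays held material pooled from 4 samples, and the labels call the 2 arrays of a cell type biological replicates. A p-value here measures the spread between such pools, not between single mice. The limits that the series text sets for its own quality control were a correlation of replicates above 0.95, together with limits on the scale factor and the ratio of 5 prime to 3 prime signal.

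The deposited values are log2 expression values, made by the authors with GCRMA per the submitters' processing notes, with 1 value for each of 45101 probe sets and each array. GCRMA corrects the background with the help of probe sequences, normalizes between arrays and summarises the probes of a set. The version, and whether all 20 arrays were processed together, are not given in the sources used here. Values ranged from 0.37 to 16.85, and array medians over all probe sets from 3.08 to 3.27. The number of arrays limits the precision, and a probe set near the background level gives no reliable difference. No further normalization was applied for the main results.

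Probe sets were named through the platform annotation supplied with the data. It gave 1 gene symbol for 34945 probe sets and several for 932. Another 9160 probe sets were not listed, which leaves them unnamed here, and 64 were controls. For 34754 probe sets the symbol was taken through a match of the Entrez identifier, whether or not this changed it. Each of the 18193 genes was represented by the probe set with the highest mean over all arrays, and 9010 genes had more than 1 to choose from. A gene was tested if at least 2 arrays had a log2 value above 5, which kept 9810 genes and left out 8383. Genes with no probe set of their own, among them Ly6g, Ly6a and Ddx3y, are not analysed here.

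Groups were taken from the sample titles in the labels, and for 1 array from its source name. The title of that array reads CD48+ where its source name reads CD8+, and it was placed with the naive CD8 T cells. A linear model with 1 mean per cell type was fitted to all 20 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which leaves 10 residual degrees of freedom. A fingerprint gene of a cell type had to exceed each of the other 9 types. The largest of the 9 one-sided p-values was adjusted by Benjamini-Hochberg over the genes tested, and a call needed an adjusted p under 0.05 and a smallest log2 difference, called the margin below, of at least 1. Shared fingerprints of all 4 T cell groups, of the naive pair and of the activated pair were built in the same way, over every pair of a group inside and a group outside the set. The contrasts of cell types were 2-sided, with an adjusted p under 0.05 and a log2 difference of at least 1 in size (2-fold).

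Before the data were examined, 29 gene lists were fixed from general knowledge of blood cells, and none was chosen on these arrays. Each was tested with camera at its preset correlation of 0.01 in 17 contrasts, 493 tests in all with Benjamini-Hochberg adjustment over them. Of these tests, 207 passed. With the correlation estimated from the residuals 8 passed, and 315 passed with fry, which asks only whether the genes of a list move one way on balance and not whether they differ from other genes. No list that passed with camera had a median or a mean of the opposite sign. The calls that held with an estimated correlation were the hematopoietic stem cell list in LT-HSC, the NK cell list in NK cells (against all others and against naive T cells), the B cell list in B cells, the T cell list in naive CD4 and in naive CD8 T cells against all others, and the CD4 and CD8 lineage lists between CD4 and CD8 T cells. The report describes 78 pairs of a list and a contrast, which were picked after the list tests were seen.

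Genes to be named were chosen by a rule written before the data were examined. It takes the 4 fingerprint genes with the largest margin per cell type and 6 per shared fingerprint, and the 10 largest differences on each side of a contrast among genes whose arrays did not overlap between the sides. It adds up to 4 members of each described list that moved with the list, up to 2 that moved against it and up to 2 that were not called, and a fixed set of genes that check the labels. Symbols of unnamed transcripts, immunoglobulin and T-cell receptor segments and the Klra family were passed over. For the genes named in contrasts, 74 other probe sets were compared, and 3 of them did not move with the one used.

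The pipeline was tested on simulated data of 9810 genes. The LT-HSC fingerprint recovered 58.2% of genes changed by a log2 difference of 2, 82.1% at 3 and 95.5% at 4, and the shared T cell fingerprint 38.8%, 70.1% and 93.9%. For the contrast of activated against naive CD4 T cells the shares were 75.8%, 89.6% and 94.0%, with 11 false calls. For LT-HSC against the other groups, and for lymphoid against myeloid cells, 89.4% were recovered at a log2 difference of 2, with 7 and 4 false calls.

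The alternatives tried were no filter, a stricter filter at log2 7, quantile normalization, median centring over the genes tested, the mean of all probe sets of a gene, every probe set on its own, a trended and robust prior, array weights, the replicate number as a block, a fit of only the groups compared, and leaving out each array in turn. Correlations between arrays were also computed as Spearman's. Alternatives added after seeing the data were the probe set with the highest group mean, leaving out the naive T cell arrays numbered 2 or those numbered 1, and leaving out the granulocyte group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.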

Results

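The series set out to describe expression fingerprints of hematopoietic stem cells and their progeny. It holds 20 arrays, 2 for each of 10 sorted mouse cell types: long-term hematopoietic stem cells (LT-HSC), natural killer (NK) cells, naive CD4 and CD8 T cells, CD4 and CD8 T cells that the labels describe as activated with lipopolysaccharide (LPS), B cells, monocytes, granulocytes and nucleated erythrocytes, the late red cell precursors that still carry a nucleus. Values are log2 GCRMA expression values. In each array between 7091 and 7904 of the 18193 genes lay above a log2 value of 5. A value after ± is the standard error (SE) of a fitted difference unless it is called SD, and every group has n = 2 arrays.

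Replicate arrays resembled each other more than they resembled any other cell type. Across the 9810 genes tested, which are not independent replicates, the correlation of the 2 arrays of a type lay between 0.945 in monocytes and 0.988 in B cells, and arrays of different types correlated between 0.509 and 0.974. The nearest array was the replicate in 20 of 20 cases, and in 19 of 20 with Spearman correlation or over all probe sets. The limit of 0.95 in the series text was exceeded in 9 of 10 types over the genes tested and in 10 of 10 over all probe sets. Monocyte arrays differed most, with 2415 genes apart by over 2-fold against 445 in B cells. As a measure of RNA quality, the Gapdh control probe set of the 5 prime end read 7.42 to 8.81 in the activated T cell arrays and 8.23 and 8.26 in the granulocyte arrays. It read 3.89 to 4.45 in the naive T cell arrays and 4.08 in monocyte array 1. It was under a log2 value of 5 in these and in the LT-HSC, NK, B cell and erythrocyte arrays. The size of the 3 prime minus 5 prime difference cannot be read in any of them. The Actb probe set of the 5 prime end read 4.10 and 3.94 in activated and 3.57 and 3.76 in naive CD4 arrays. All lie under 5, so these values cannot show or exclude a shift. In CD8 T cells it read 5.55 and 4.80 in the activated and 3.89 and 3.86 in the naive arrays, and in granulocytes 9.15 and 7.59.

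Genes that identify the sorted populations were read first, as a check of the labels. Cd8a, the alpha chain of the CD8 co-receptor, averaged 13.36 ± 0.11 (SD) in naive and 12.66 ± 0.35 (SD) in activated CD8 T cells and at most 5.63 in any other type. Cd8b1, its partner chain, averaged 12.25 and 9.88 in the same groups. Cd3e, a signalling chain of the T-cell receptor complex, lay between 7.78 and 9.04 in the 4 T cell groups and at 4.38 or below elsewhere. Ncr1, an activating receptor of NK cells, averaged 10.20 ± 0.54 (SD) in NK cells, and no other array exceeded 2.33. Itgam, an integrin chain of myeloid and NK cells, averaged 8.90 in monocytes, 8.31 in granulocytes and 5.36 in NK cells. Kit, the stem cell factor receptor, was highest in LT-HSC at 9.73. Csf1r, the receptor for macrophage colony-stimulating factor, was highest in monocytes at 13.83 and in granulocytes at 12.74, and was also at 7.70 or above in LT-HSC, NK, B and naive T cells and erythrocytes. Another of its 3 probe sets read 2.43 or below in those groups, 6.40 in monocytes and 3.60 in granulocytes. Cd4 was not tested: the probe set with the highest mean over all arrays did not pass the filter, and its other probe set averaged 6.74 ± 0.56 (SD) in naive CD4 T cells and 3.49 ± 0.88 (SD) in activated CD4 T cells. Klrb1c had no probe set of its own, and the one listed for it and Klrb1b read 12.65 and 11.80 in the NK arrays.

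Y-linked transcripts were present in 6 T cell arrays although the labels give female mice. Eif2s3y, a Y-linked translation factor gene, and Kdm5d, a Y-linked histone demethylase gene, were at 10.73 and 7.71 or above in both activated CD4 arrays, both activated CD8 arrays and the naive CD4 and CD8 arrays numbered 1. They were at or below 3.45 and 2.72 in the other 14 arrays. Xist, the RNA that coats the inactive X chromosome of female cells, lay between 2.23 and 9.88 in these 6 arrays and between 9.50 and 13.47 in the other 14, and in 3 of the 6 it was under 5. These values come from the brightest of its 3 probe sets. Another was under 5 in all 6 arrays, but also in naive CD4 array 2 (3.76), naive CD8 array 2 (4.49), monocyte array 1 (3.69) and granulocyte array 2 (4.40). The activated groups therefore carried the Y-linked signal in all 4 of their arrays, and each naive group in 1 of 2.

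**Figure D1:**
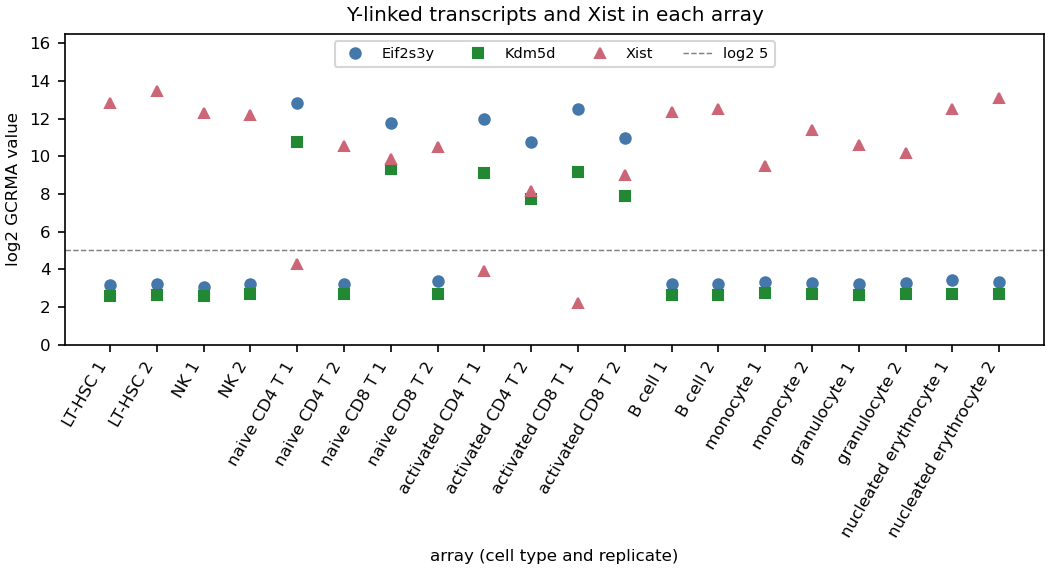
Expression (log2 GCRMA value, vertical axis) of the Y-linked genes Eif2s3y and Kdm5d and of Xist in each of the 20 arrays (horizontal axis), with 1 point per array and gene and a dashed line at a log2 value of 5. Eif2s3y and Kdm5d lie above the line in 6 T cell arrays and below it in the other 14.

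Which genes mark a single cell type was the question that the series title names. Fingerprints, the genes above all 9 other types, ranged from 717 genes in nucleated erythrocytes and 359 in LT-HSC to 6 in naive CD4 and 6 in activated CD4 T cells. Granulocytes had 195, monocytes 134, B cells 125, NK cells 112, activated CD8 T cells 14 and naive CD8 T cells 13. Related T cell groups resemble each other (mean correlation of arrays 0.961 between the naive and 0.969 between the activated pair), and genes they share cannot enter the fingerprint of a single group. Fits of only the groups compared have 2 residual degrees of freedom for a pair and take the spread from that pair alone. In them the 4 T cell and the monocyte fingerprints had 0 genes, with 49 to 351 genes at an unadjusted limma p under 0.05. The counts were then 281 in erythrocytes, 121 in LT-HSC, 26 in NK cells, 6 in granulocytes and 3 in B cells, and with a stricter filter 229 in LT-HSC. Without the granulocyte group the monocyte fingerprint held 568 genes.

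**Figure D2:**
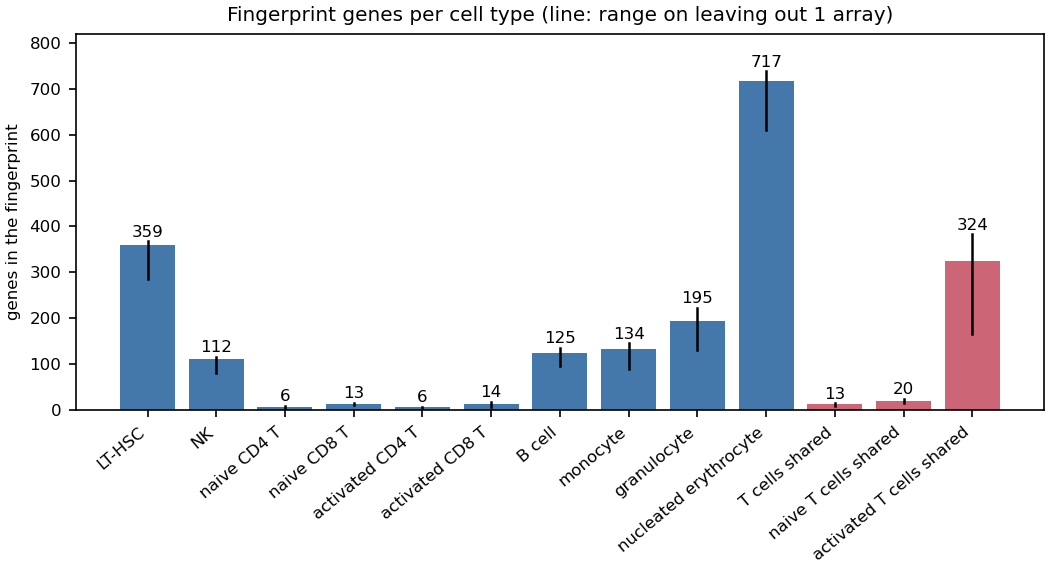
Number of fingerprint genes (vertical axis, bars) for each of the 10 cell types and the 3 shared T cell sets, with a line from the lowest to the highest count when any 1 of the 20 arrays is left out. Nucleated erythrocytes have the most with 717, and the naive and activated CD4 T cells the fewest with 6 each.

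LT-HSC were marked by Mecom, a transcription factor needed for stem cell maintenance, with a margin of 9.95 ± 0.19, adjusted p = 5.90e-13. Myct1 (9.50 ± 0.19), Mmrn1, a platelet and endothelial protein (9.08 ± 0.19), and Cd34, a progenitor surface sialomucin (8.80 ± 0.19), followed. Of the hematopoietic stem cell list 14 of 22 tested members were in this fingerprint, and of the imprinted genes 5 of 10. NK cells were marked by lectin-like receptors: Klre1 (10.45 ± 0.31, adjusted p = 2.94e-11), Klrb1a (9.46 ± 0.23) and Klrk1, which encodes NKG2D (8.89 ± 0.25), with Klhl30 (8.33 ± 0.17) next. All 20 tested NK cell list members were higher in NK cells than in the mean of the other types (20 adjusted over the list alone, camera adjusted p = 8.19e-21 and adjusted p = 0.0218 with an estimated correlation), and 11 were fingerprint genes. B cells were marked by Fcmr, the Fc receptor for IgM (9.43 ± 0.29, adjusted p = 9.00e-11), Fcer2a, the low-affinity IgE receptor (8.53 ± 0.48), S1pr3 (7.93 ± 0.19) and the kinase gene Srpk3 (7.83 ± 0.78). Here 22 of 22 tested B cell list members were higher than in the other types (22 adjusted over the list alone, camera adjusted p = 3.49e-21 and adjusted p = 0.0127 with an estimated correlation), 18 of them fingerprint genes. MHC class II genes, which encode the antigen-presenting molecules, were higher in 8 of 8 (8 adjusted over the list alone, camera adjusted p = 4.43e-07 and adjusted p = 0.154 with an estimated correlation), led by H2-DMb2 (8.16 ± 0.34). Of the plasma cell list 3 of 6 were higher (3 adjusted over the list alone, camera adjusted p = 0.017 and adjusted p = 0.184 with an estimated correlation). These were Mzb1 (6.32 ± 0.13), Sdc1 (4.92 ± 0.30) and Jchain (4.39 ± 0.86).

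Nucleated erythrocytes were marked by Agtr1a, an angiotensin receptor gene (10.32 ± 0.17, adjusted p = 1.02e-13), the amino acid transporter gene Slc38a5 (9.84 ± 0.55), Klf1, the erythroid transcription factor that drives adult globin genes (9.81 ± 0.69), and Slc22a23 (9.73 ± 0.32). Erythroid genes were higher than in the other types in 19 of 19 tested members (19 adjusted over the list alone, camera adjusted p = 2.05e-17 and adjusted p = 0.184 with an estimated correlation), 18 of them fingerprint genes. Heme synthesis enzymes and carriers were higher in 9 of 9 (9 adjusted over the list alone, camera adjusted p = 1.30e-08 and adjusted p = 0.0672 with an estimated correlation), with Alas2, the first enzyme of the pathway, at 12.08 ± 0.26. Cell cycle genes were higher in 36 of 37 (36 adjusted over the list alone, camera adjusted p = 1.97e-18 and adjusted p = 0.184 with an estimated correlation), led by Ube2c (8.98 ± 0.32) and Ccnb2 (8.20 ± 0.55). Granulocytes were marked by the integrin gene Itgb2l (7.78 ± 0.30, adjusted p = 8.84e-10), Tmem45a2 (7.76 ± 0.17), Ano10 (7.36 ± 0.17) and Cldn1, a tight junction protein gene (6.52 ± 0.17). Their fingerprint held 7 of 11 tested secondary and tertiary granule genes and 3 of 4 primary granule genes. Erythroid genes were also higher in granulocytes than in the mean of the other types in 11 of 19 members (11 adjusted over the list alone, camera adjusted p = 0.00216 and adjusted p = 0.564 with an estimated correlation).

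Monocytes were marked by Ttc30a2, a gene of ciliary transport (6.29 ± 0.18, adjusted p = 1.87e-10), Zfyve9, an adaptor of TGF-beta signalling (5.99 ± 0.27), the receptor gene Gpr35 (5.66 ± 0.26) and Ace, which encodes angiotensin-converting enzyme (5.48 ± 0.65). The SD of Ace was 2.28 in monocytes and at most 0.064 in any other type, so its SE understates the spread between the monocyte arrays. Against the mean of the other types, mature neutrophil genes were higher in monocytes in 13 of 13 tested members (13 adjusted over the list alone, camera adjusted p = 2.33e-10 and adjusted p = 0.184 with an estimated correlation). Clec4d (10.09 ± 1.03) and S100a9 (9.99 ± 1.18) led them. Interferon response genes were higher in 15 of 21 and lower in 1 (15 adjusted over the list alone, camera adjusted p = 1.93e-06 and adjusted p = 0.205 with an estimated correlation), led by Oasl2 (6.28 ± 0.37) and Oas2 (5.10 ± 0.29). Genes of the LPS and NF-kB response were higher in 8 of 12 (8 adjusted over the list alone, camera adjusted p = 3.66e-04 and adjusted p = 0.282 with an estimated correlation). Il1b (11.10 ± 0.47) and Cd14, the LPS co-receptor gene (7.75 ± 0.75), were among them. The mean level of this list was 11.78 in monocyte array 1 and 9.65 in array 2. With each array centred on its median the monocyte fingerprint held 306 genes in place of 134, and with array weights 77.

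Among T cells, 13 genes exceeded every other type in all 4 groups. They were led by the surface receptors Cd6 (6.72 ± 0.21, adjusted p = 5.30e-10) and Cd5 (6.43 ± 0.55), the kinase gene Camk4 (4.93 ± 0.27), the T-cell receptor complex chains Cd3g (4.25 ± 0.40) and Cd3e (3.40 ± 0.25), and Themis, a gene needed for thymocyte selection (3.56 ± 0.59). Of the T cell list 8 of 20 tested members were in this set. The call of Themis was lost under 7 other settings. Naive T cells of both lineages shared 20 genes. At their head were Slc16a5, a member of the monocarboxylate transporter family (5.69 ± 0.28, adjusted p = 1.57e-07), Nsg2 (5.44 ± 0.43), Ampd1, an AMP deaminase gene (4.94 ± 0.58), Ccr9, a gut-homing chemokine receptor (4.88 ± 0.44), Dzip1 (4.36 ± 0.42) and Gabrr2, a GABA receptor subunit gene (4.32 ± 0.63). Among these, the naive CD4 arrays varied most in Gabrr2 (SD 2.20) and Ampd1 (SD 1.90). Activated T cells shared 324 genes, led by Il2ra, the alpha chain of the interleukin 2 receptor (8.40 ± 0.25, adjusted p = 1.07e-10), and the amino acid enzyme genes Bcat1 (7.65 ± 0.18) and Cth (6.01 ± 0.42). The lipid transporter gene Mfsd2a (5.01 ± 0.38), Ruvbl2 (4.82 ± 0.38) and Znrd2 (4.76 ± 0.28) came next, and 12 of 20 tested ribosome biogenesis genes and 5 of 12 cholesterol synthesis genes were in the set. Its count fell to 215 without naive CD8 array 1, 211 without naive CD8 array 2 and 165 without activated CD4 array 1. Leaving out the naive arrays numbered 1, which carried the Y-linked signal, gave 192 genes and leaving out those numbered 2 gave 182. In limma fits of only the groups compared each of the shared sets had 0 genes, with 70, 85 and 911 at an unadjusted p under 0.05 for all, naive and activated T cells.

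Single T cell groups had few genes of their own. Naive CD4 T cells were marked by Pdlim4, a cytoskeletal adaptor gene (4.48 ± 0.25, adjusted p = 7.27e-07), Il17rb, a receptor chain for interleukin 25 (3.18 ± 0.50, adjusted p = 0.0334), the transcription factor gene Tox2 (2.80 ± 0.47, adjusted p = 0.0432) and Matn2 (2.67 ± 0.45, adjusted p = 0.0432). Naive CD8 T cells were marked by Itgae, the CD103 integrin chain that binds E-cadherin (5.39 ± 0.62, adjusted p = 5.42e-04), the amino acid transporter gene Slc6a19 (4.87 ± 0.18), Lcn4 (4.30 ± 0.20) and the potassium channel gene Kcna2 (4.28 ± 0.29). Activated CD4 T cells were marked by Tnfrsf4, the co-stimulatory receptor OX40 (3.47 ± 0.54, adjusted p = 0.0207), Akr1c18 (3.27 ± 0.25) and the cytokine genes Il4 (2.89 ± 0.49, adjusted p = 0.0439) and Il2 (2.87 ± 0.38, adjusted p = 0.00658). Activated CD8 T cells were marked by the meiosis gene Mei4 (3.55 ± 0.21, adjusted p = 1.69e-06), the transcriptional repressor gene Zbtb32 (3.34 ± 0.24), Cd320, the receptor for transcobalamin-bound vitamin B12 (2.94 ± 0.34), and Pmm1 (2.45 ± 0.40). The naive CD4 count was 3 without any 1 of 12 arrays (LT-HSC, NK, B cell, granulocyte and erythrocyte arrays 1 and 2, naive CD8 array 1 and activated CD8 array 1), and Il17rb, Tox2 and Matn2 lost their calls under at least 20 settings, as did Il4 in activated CD4 T cells. The activated CD4 count was 3 and 2 without activated CD4 array 1 and 2, and that of activated CD8 T cells 7 to 9 without activated CD8 array 2, B cell array 2, granulocyte array 1 or 2, or erythrocyte array 2. Pmm1 lost its call under 9 settings and Tnfrsf4 under 6.

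**Figure D3:**
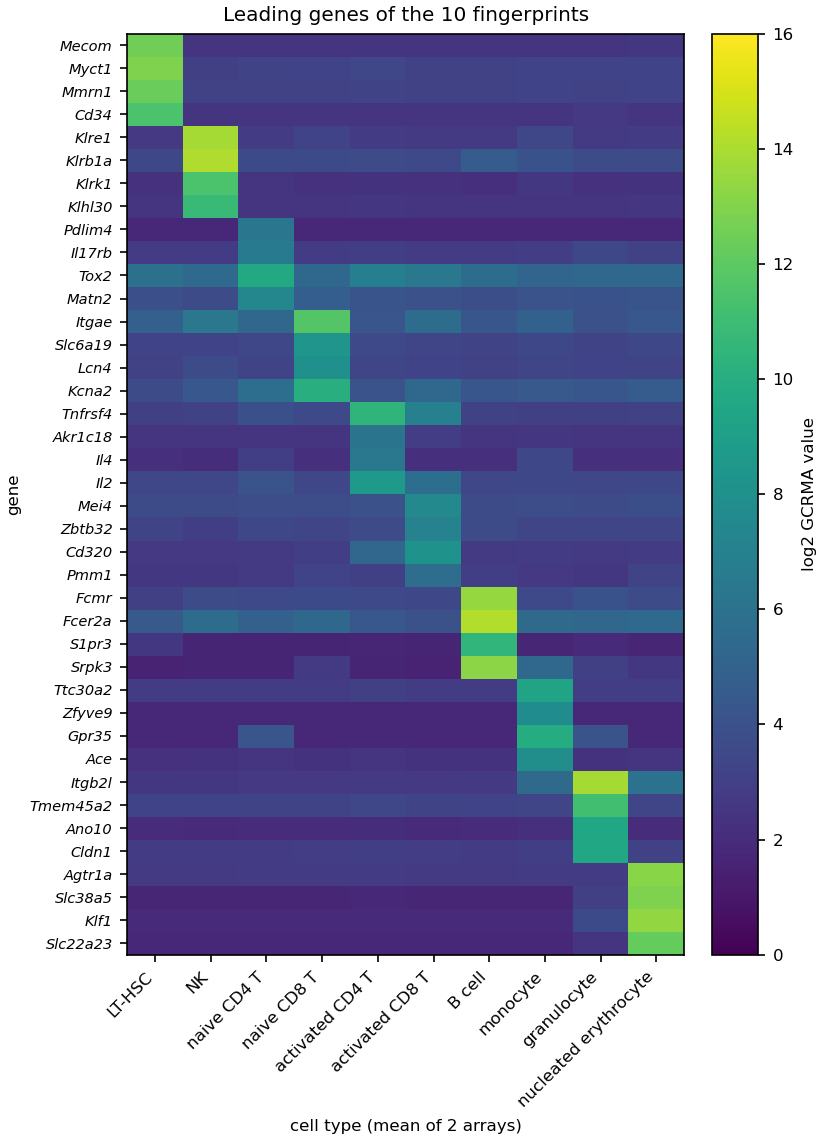
Mean expression (log2 GCRMA value, colour scale from 0 to 16) of the 4 leading fingerprint genes of each cell type (rows) in the 10 cell types (columns, each the mean of 2 arrays). Each block of 4 genes is brightest in its own cell type; Mecom reads 12.56 in LT-HSC and Klf1 13.42 in nucleated erythrocytes.

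What sets LT-HSC apart from the average of their progeny was the next comparison. The genes named first in this and the later comparisons have large differences among genes whose arrays did not overlap between the sides, and others as large are not all given. In LT-HSC 1803 genes were higher and 2109 lower than in the mean of the other 9 types. Hoxa9, a homeobox gene of early hematopoietic cells (10.72 ± 0.74, adjusted p = 6.56e-08), Bex1 (10.19 ± 0.47), Mecom (10.09 ± 0.14) and Myct1 (9.69 ± 0.14) were among the higher genes, and Fkbp9, Mmrn1, Mamdc2, Cd34, Ctla2b and Mmp2 lay between 8.75 and 9.39. Lower were Cmah, which makes N-glycolylneuraminic acid (-8.73 ± 0.97), the interferon-inducible gene Ifi209 (-8.61 ± 0.58), Ms4a4c (-8.12 ± 0.68), Rasgrp1, an activator of Ras in lymphocytes (-8.11 ± 0.53), and Cd48, a surface protein whose absence is used to sort stem cells (-7.12 ± 0.87). Il7r, the interleukin 7 receptor chain of lymphoid cells (-7.37 ± 0.49), and Ikzf3, a lymphoid transcription factor gene (-7.96 ± 0.38), were lower too.

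By lists, 21 of 22 tested hematopoietic stem cell genes were higher in LT-HSC (21 adjusted over the list alone, camera adjusted p = 8.92e-17 and adjusted p = 0.0258 with an estimated correlation), including Fgd5 (8.73 ± 0.14) and Meis1 (8.63 ± 0.40). Slamf1 did not pass (-0.43 ± 0.25, adjusted p = 0.164). Imprinted genes, expressed from 1 parental allele, were higher in 7 of 10 and lower in 1 (7 adjusted over the list alone, camera adjusted p = 6.22e-05 and adjusted p = 0.0516 with an estimated correlation). Among them were Grb10 (7.10 ± 0.25), Plagl1 (6.85 ± 0.33) and Meg3 (6.36 ± 0.21) above and Igf2r below (-1.26 ± 0.23). Immediate early and heat shock genes, which respond within minutes to handling or stress, were higher in 10 of 13 (11 adjusted over the list alone, camera adjusted p = 9.32e-04 and adjusted p = 0.31 with an estimated correlation). Fosb (6.71 ± 1.28) and Fos (4.63 ± 0.74) led them. Efflux transporters (3 of 6 higher, 3 adjusted over the list alone) and megakaryocyte and platelet genes (4 of 10 higher, 4 adjusted over the list alone) did not pass as lists (camera adjusted p = 0.139 and 0.0608). Their members Abcg2, the dye pump of the stem cell side population (3.69 ± 0.50), Vwf, the von Willebrand factor gene (6.08 ± 0.47), and Pf4, a platelet chemokine gene (4.89 ± 0.63), were higher. T cell genes were lower in 18 of 20 and higher in 1 (18 adjusted over the list alone, camera adjusted p = 2.72e-08 and adjusted p = 0.105 with an estimated correlation). NK cell genes were lower in 17 of 20 (17 adjusted over the list alone, camera adjusted p = 2.08e-06 and adjusted p = 0.184 with an estimated correlation). B cell genes were lower in 16 of 22 (16 adjusted over the list alone, camera adjusted p = 0.00175 and adjusted p = 0.266 with an estimated correlation). Tnfrsf13c, the BAFF receptor gene, went the other way (4.28 ± 0.48). Interferon response genes were lower in 10 of 21 and higher in 1 (11 adjusted over the list alone, camera adjusted p = 0.0205 and adjusted p = 0.473 with an estimated correlation), for example Usp18 (-5.63 ± 0.35). Cell cycle genes went both ways, with 4 higher and 10 lower of 37 (4 and 9 adjusted over the list alone, camera adjusted p = 0.797). The median of all genes was -0.20 in this contrast and -0.30 after quantile normalization.

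The effect of activation was read in CD4 T cells by comparing activated with naive cells. Activation went with 1465 genes up and 1785 down, or 45.1% up, and with 54.0% up after median centring. Asns, which makes asparagine, rose most (9.12 ± 0.45, adjusted p = 3.75e-08). It was followed by Il2ra (8.48 ± 0.25), the alanine transaminase gene Gpt2 (7.81 ± 0.72), the branched-chain transaminase gene Bcat1 (7.69 ± 0.18) and Irf4, a transcription factor induced by antigen receptor signals (7.28 ± 0.83). Ccl22, Tnfrsf4, Bex1, Plagl1 and Tnfrsf9 rose by 6.16 to 6.89. H2-Ob, a regulator of MHC class II peptide loading, fell most (-8.49 ± 1.18, adjusted p = 1.11e-04), and Tmem71 (-8.43 ± 0.85), Ifi213 (-8.13 ± 1.01), the phosphodiesterase family gene Smpdl3a (-7.94 ± 0.56) and Rasa3 (-7.81 ± 0.96) fell with it. Klrd1, Syne1, Pik3ip1, Csf1r and Cmah fell by values between -7.67 and -7.18. For Syne1, Csf1r and Cmah a further probe set did not fall (0.04, 0.53 and 0.02). That of Csf1r read 2.29 in naive and 2.82 in activated CD4 T cells, so low that little fall could be measured. Of the genes named here as falling, Tmem71, Smpdl3a, Syne1 and Csf1r read higher in granulocytes than in naive CD4 T cells. H2-Ob, Ifi213, Rasa3, Klrd1, Pik3ip1 and Cmah read lower in granulocytes. Whether the falls took place within the T cells was not tested. Median centring moved the median of all genes from 0.02 to 0.22 in this contrast.

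Genes of T cell activation rose in 17 of 26 tested members (18 adjusted over the list alone, camera adjusted p = 5.05e-08 and adjusted p = 0.184 with an estimated correlation), whereas Ifng did not pass (2.44 ± 0.93, adjusted p = 0.0551). Ribosome biogenesis genes rose in 18 of 20 (19 adjusted over the list alone, camera adjusted p = 2.65e-09 and adjusted p = 0.102 with an estimated correlation), led by Polr1b, a subunit of RNA polymerase I (4.74 ± 0.54), and Nhp2 (3.55 ± 0.40). Glycolysis genes rose in 9 of 11 (9 adjusted over the list alone, camera adjusted p = 1.32e-05 and adjusted p = 0.248 with an estimated correlation), with Tpi1 (5.13 ± 0.53) and Hk2, the inducible hexokinase (4.96 ± 0.50), in front. Cholesterol synthesis genes rose in 9 of 12 (10 adjusted over the list alone, camera adjusted p = 3.50e-05 and adjusted p = 0.214 with an estimated correlation), with Msmo1 at 3.65 ± 0.70 and Cyp51 at 3.01 ± 0.46. Cell cycle genes did not pass as a list (camera adjusted p = 0.165). Of 37 members 9 rose and 3 fell (8 and 3 adjusted over the list alone), the replication genes Cdc6 (2.99 ± 0.83) and Mcm5 (2.95 ± 0.34) among the first and Mki67 (-2.60 ± 0.72) among the second. The LPS and NF-kB response list did not pass either (0.838), with 1 of 12 up, Nfkb2 (3.04 ± 0.35), and 2 down (1 and 2 adjusted over the list alone).

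Several lists fell with activation of CD4 T cells. Interferon response genes fell in 14 of 21 and 1 rose (14 adjusted over the list alone, camera adjusted p = 5.29e-04 and adjusted p = 0.315 with an estimated correlation). Rsad2 (-5.28 ± 0.48) and Ddx58, the RNA sensor RIG-I (-4.98 ± 0.39), fell most among them. Naive T cell genes fell in 9 of 16 and 1 rose (10 adjusted over the list alone, camera adjusted p = 0.00181 and adjusted p = 0.239 with an estimated correlation). Txnip, an inhibitor of glucose uptake (-5.52 ± 0.47), and Il7r (-3.68 ± 0.65) were 2 of them. T cell genes fell in 11 of 20 (11 adjusted over the list alone, camera adjusted p = 0.00226 and adjusted p = 0.282 with an estimated correlation), for example Cd3g (-2.81 ± 0.40). MHC class II genes fell in 7 of 8 (7 adjusted over the list alone, camera adjusted p = 0.00115 and adjusted p = 0.266 with an estimated correlation), with H2-Ab1 at -4.06 ± 0.95. Markers of other cell types moved with them. Monocyte and macrophage genes fell in 10 of 20 (10 adjusted over the list alone, camera adjusted p = 0.00666 and adjusted p = 0.448 with an estimated correlation). Dendritic cell genes fell in 4 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0131 and adjusted p = 0.221 with an estimated correlation). The largest fall among them was that of Ccr9 (-4.88 ± 0.44), which was also a naive T cell fingerprint gene. B cell genes fell in 6 of 22 and 1 rose, which did not pass as a list (5 adjusted over the list alone, camera adjusted p = 0.185). Activated arrays also differed from the naive ones in the Gapdh 5 prime signal and in the Y-linked signal given above. The Actb 5 prime signal was under a log2 value of 5 in every CD4 array, so a shift cannot be read from it.

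The same comparison in CD8 T cells gave 1411 genes up and 1536 down, or 47.9% up, and 52.8% up after median centring. Asns (9.49 ± 0.45, adjusted p = 1.71e-08), Il2ra (9.20 ± 0.25), Bcat1 (8.45 ± 0.18), Gpt2 (8.04 ± 0.72) and Cth (7.87 ± 0.42) rose most. They were followed by Irf4 (7.76 ± 0.83), Tnfrsf9, a co-stimulatory receptor (7.31 ± 0.43), Rgs16 (6.90 ± 0.50), the cytotoxic protease gene Gzmb (6.68 ± 1.15) and the chemokine gene Ccl3 (6.65 ± 1.19). Plbd1 fell most (-8.09 ± 0.90, adjusted p = 2.59e-05), and with it H2-Ob (-7.30 ± 1.18), Baiap3 (-7.26 ± 0.48), Lypd6b (-7.24 ± 0.61) and Smpdl3a (-7.06 ± 0.56). Hsd11b1, Alox5ap, Ccr9, Cmah and Gzma fell by values between -6.94 and -6.31. Plbd1 read 13.98 in granulocytes and 9.53 in naive CD8 T cells, and Alox5ap 14.70 and 9.21. Smpdl3a and Hsd11b1 also read higher in granulocytes, whereas H2-Ob, Baiap3, Lypd6b, Ccr9, Cmah and Gzma read lower there. Whether the falls took place within the T cells was not tested.

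T cell activation genes rose in 19 of 26 (19 adjusted over the list alone, camera adjusted p = 2.68e-11 and adjusted p = 0.105 with an estimated correlation). Ribosome biogenesis genes rose in 18 of 20 (18 adjusted over the list alone, camera adjusted p = 4.65e-09 and adjusted p = 0.104 with an estimated correlation). Glycolysis genes rose in 8 of 11 (9 adjusted over the list alone, camera adjusted p = 3.64e-05 and adjusted p = 0.266 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 12 (10 adjusted over the list alone, camera adjusted p = 7.08e-07 and adjusted p = 0.184 with an estimated correlation). Sqle, the squalene epoxidase gene, rose by 5.59 ± 0.56. Cell cycle genes rose in 13 of 37 and 1 fell (15 adjusted over the list alone, camera adjusted p = 0.00106 and adjusted p = 0.52 with an estimated correlation). Cdc6 (4.33 ± 0.83), Cdk1 (3.16 ± 0.83) and E2f1 (2.86 ± 0.58) were among those that rose. Interferon response genes fell in 14 of 21 (14 adjusted over the list alone, camera adjusted p = 1.78e-05 and adjusted p = 0.242 with an estimated correlation). Naive T cell genes fell in 9 of 16 (10 adjusted over the list alone, camera adjusted p = 5.29e-04 and adjusted p = 0.199 with an estimated correlation). A fall was also seen for T cell genes in 8 of 20 (8 adjusted over the list alone, camera adjusted p = 0.00743 and adjusted p = 0.328 with an estimated correlation). MHC class II genes fell in 7 of 8 (7 adjusted over the list alone, camera adjusted p = 1.62e-04 and adjusted p = 0.214 with an estimated correlation). Members of these lists that fell were Ifit3 (-4.18 ± 0.57), Klf2, a transcription factor of quiescent T cells (-4.48 ± 0.76), and H2-Oa (-4.95 ± 0.63). Markers of other cell types fell as well. Monocyte and macrophage genes did so in 6 of 20 (6 adjusted over the list alone, camera adjusted p = 0.031 and adjusted p = 0.527 with an estimated correlation), and dendritic cell genes in 4 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0131 and adjusted p = 0.221 with an estimated correlation). B cell genes fell in 5 of 22 (4 adjusted over the list alone, camera adjusted p = 0.0342 and adjusted p = 0.42 with an estimated correlation), for example Cd72 (-5.19 ± 0.80). Of the LPS and NF-kB response list 2 of 12 rose, Tnf (3.55 ± 0.98) and Nfkb2 (2.44 ± 0.35), and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.932). Activated CD8 arrays also read higher than the naive ones in the Gapdh and Actb 5 prime signals, with Actb at 5.55 and 4.80 against 3.89 and 3.86.

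Whether activation acted alike in both lineages was tested as the difference of its effects. Of the 3875 genes called in at least 1 lineage 1096 rose in both, where independent lists would share 211, and 1224 fell in both, where independent lists would share 279. Only 2 genes moved in opposite directions, and the effects correlated with r = 0.879 across genes. For 928 genes the call was made in CD4 alone and for 625 in CD8 alone, which does not show that the effects differ. The difference itself passed for 65 genes, 32 with a higher effect in CD8 and 33 in CD4. Ccl4, a chemokine gene of cytotoxic cells, rose by 5.09 in CD8 and had a value of -0.31 in CD4 T cells (difference 5.40 ± 0.60, adjusted p = 3.16e-04). Xcl1, another chemokine gene, rose by 4.04 in CD8 against a value of 0.08 in CD4 (3.97 ± 0.40, adjusted p = 1.80e-04). Klrd1, a lectin-like receptor gene, fell by 3.38 in CD8 and had a value of -7.67 in CD4 (4.29 ± 0.78, adjusted p = 0.0209). Pik3ap1, a signalling adaptor gene, fell by 3.66 in CD4 and had a value of 0.18 in CD8 (3.85 ± 0.68, adjusted p = 0.0169). The call of Klrd1 was lost under 8 other settings and that of Pik3ap1 under 6. Of the 65 genes 32 fell in 1 lineage and lay under a log2 value of 5 throughout the other, where little fall could be measured. Tlr3, a sensor of double-stranded RNA, was such a gene, with 8.62 in naive CD8 and 3.54 in naive CD4 T cells. Cell cycle genes as a list had a higher effect in CD8 (median difference 0.68, camera adjusted p = 0.00875 and adjusted p = 0.624 with an estimated correlation). Members such as Tpx2 did not pass singly (3.32 ± 1.63, adjusted p = 0.834). Cholesterol synthesis genes passed as a list too (median 0.32, camera adjusted p = 0.046 and adjusted p = 0.483 with an estimated correlation, 1 of 12 members higher adjusted over the list alone), though Sqle did not pass over all genes (adjusted p = 0.16). A fit of only the 4 T cell groups called 22 genes in place of 65.

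**Figure D4:**
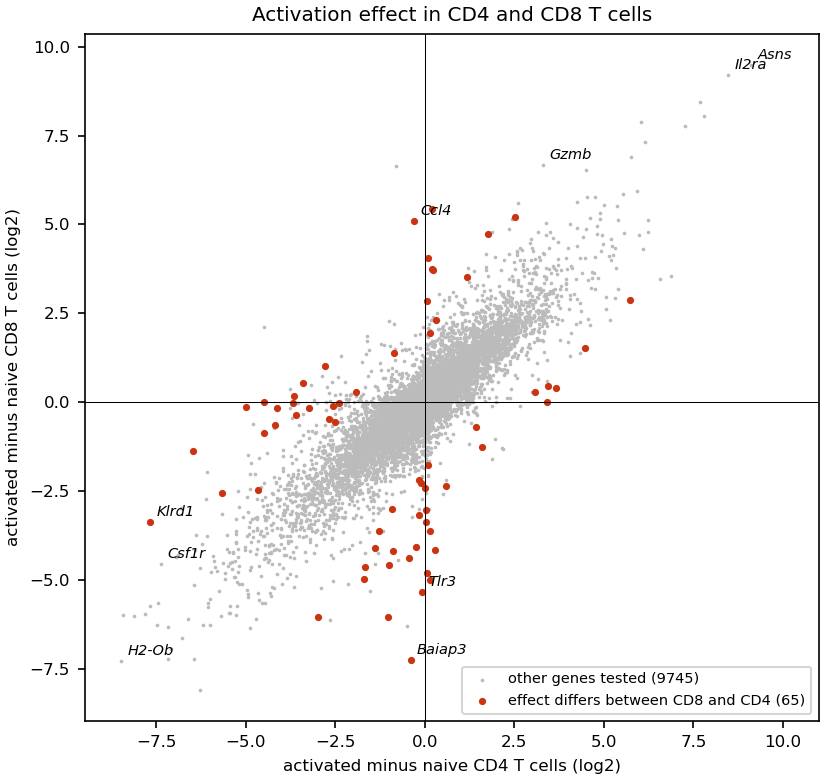
Log2 difference on activation in CD4 T cells (horizontal axis) against that in CD8 T cells (vertical axis), 1 point per gene. The 65 genes whose effect differed between the lineages are red, the other tested genes grey, and r across all genes is 0.879.

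CD4 and CD8 T cells were compared over naive and activated cells together, and 90 genes were higher in CD4 and 231 in CD8. Cd8a (-7.79 ± 0.22, adjusted p = 1.22e-10) and Cd8b1 (-7.69 ± 0.19) were higher in CD8, as was Nkg7, a cytotoxic granule membrane gene (-5.98 ± 0.56). Also higher in CD8 were the ubiquitin ligase gene Nedd4 (-4.70 ± 0.38), the protease gene Ctsw (-4.42 ± 0.19) and Cd160 (-4.40 ± 0.22). Maf, a transcription factor of cytokine-producing helper cells, was higher in CD4 (5.66 ± 0.62, adjusted p = 1.22e-04). Also higher in CD4 were Zbtb16 (2.94 ± 0.36), Trat1, an adaptor of the T-cell receptor (2.61 ± 0.28), Il1r2 (2.53 ± 0.56), Il4 (2.53 ± 0.35) and Fasl (2.41 ± 0.47). The call of Il1r2 was lost under 7 other settings. CD4 lineage genes were higher in CD4 in 5 of 6 tested members (5 adjusted over the list alone, camera adjusted p = 2.33e-10 and adjusted p = 0.0126 with an estimated correlation). Among these were Ctla4 (2.34 ± 0.42) and Zbtb7b, which encodes the CD4 lineage factor ThPOK (1.91 ± 0.20). CD8 lineage genes were lower in CD4 in 9 of 10 (9 adjusted over the list alone, camera adjusted p = 2.95e-23 and adjusted p = 0.0126 with an estimated correlation), while Runx3 did not pass (-0.50 ± 0.31, adjusted p = 0.478). NK cell genes were lower in CD4 in 9 of 20 and higher in 1 (9 adjusted over the list alone, camera adjusted p = 1.54e-04 and adjusted p = 0.238 with an estimated correlation), for example Klrd1 (-4.71 ± 0.39). Mature neutrophil genes had a median of 0.88 towards CD4 (camera adjusted p = 1.74e-04 and adjusted p = 0.327 with an estimated correlation). Of 13 members 1 was called, Il1r2 (1 adjusted over the list alone). The mean level of the list was 6.58 in naive CD4 array 2 against 3.52 in array 1.

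The share of the genes that were higher in CD4 depended on the scaling: it was 28.0% with the deposited values, 38.2% after quantile normalization and 51.5% with each array centred on its median, which moved the median of all genes from -0.10 to 0.17. The count was 208 with the mean of all probe sets of a gene, 183 without the naive arrays numbered 1 and 140 in a fit of the T cell groups alone.

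NK cells were compared with naive T cells, the closest resting lymphocytes by correlation (0.894 between NK and naive CD8), and 819 genes were higher in NK cells and 878 lower. Klre1 (10.86 ± 0.27, adjusted p = 4.03e-12), Klrb1a (10.49 ± 0.20), Styk1 (9.26 ± 0.23), Klrk1 (9.13 ± 0.22) and the sphingosine 1-phosphate receptor gene S1pr5 (8.67 ± 0.58) were higher in NK cells, and Klrc1, Klhl30, Gzma, Ncr1 and Klf12 lay between 7.74 and 8.41. Tdrp (-8.86 ± 0.49, adjusted p = 1.55e-08), Cd5 (-8.72 ± 0.48), Tlr1 (-8.37 ± 0.81), Igfbp4 (-8.05 ± 0.22) and Lypd6b (-7.88 ± 0.53) were lower, and Cd6, Dapl1, Ifi27l2a, Cd3g and Fam169b lay between -7.68 and -7.30. NK cell genes were higher in 19 of 20 (20 adjusted over the list alone, camera adjusted p = 2.33e-25 and adjusted p = 0.0127 with an estimated correlation), Ccl5 being the member that did not pass (2.62 ± 0.89, adjusted p = 0.0539). T cell genes were lower in 13 of 20 and 1 was higher (13 adjusted over the list alone, camera adjusted p = 2.32e-11 and adjusted p = 0.0635 with an estimated correlation). The higher one was Gata3, a transcription factor gene of T and innate lymphoid cells (3.13 ± 0.42). Naive T cell genes were lower in 7 of 16 and higher in 1 (7 adjusted over the list alone, camera adjusted p = 0.00116 and adjusted p = 0.222 with an estimated correlation), for example Ccr7, the lymph node homing receptor (-7.13 ± 0.23). Interferon response genes were lower in 11 of 21 (12 adjusted over the list alone, camera adjusted p = 1.23e-04 and adjusted p = 0.282 with an estimated correlation), with Oas2 at -5.02 ± 0.34. MHC class II genes were lower in 8 of 8 (8 adjusted over the list alone, camera adjusted p = 1.83e-05 and adjusted p = 0.184 with an estimated correlation), with H2-Ab1 at -5.21 ± 0.82. After median centring 50.8% of the called genes were higher in NK cells, against 48.3% with the deposited values. Without NK array 1 the contrast called 1083 genes in place of 1697.

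Monocytes and granulocytes were compared as the sorted myeloid types. In monocytes 685 genes were higher and 1702 lower. S1pr5 (7.96 ± 0.67, adjusted p = 1.89e-06), Cd14 (7.76 ± 1.01), Nr4a1, a nuclear receptor needed by patrolling monocytes (7.50 ± 0.32), Apoe (6.69 ± 0.45) and the heat shock genes Hspa1a (6.51 ± 1.26) and Hspa1b (6.28 ± 1.19) were higher in monocytes. Granulocytes were higher in Camp, the cathelicidin of secondary granules (-11.13 ± 0.50, adjusted p = 3.44e-09), Mpo, the myeloperoxidase of primary granules (-10.24 ± 0.32), Prom1 (-10.18 ± 0.32), the proliferation marker Mki67 (-9.82 ± 0.72) and the heme synthesis gene Alas2 (-9.19 ± 0.35). Rrm2, Erg, Itgb2l and Slc4a1 were between -8.92 and -8.24.

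Granule genes separated the myeloid types. Primary granule genes were lower in monocytes in 4 of 4 (4 adjusted over the list alone, camera adjusted p = 3.41e-06 and adjusted p = 0.138 with an estimated correlation). Secondary and tertiary granule genes were lower in 9 of 11 (9 adjusted over the list alone, camera adjusted p = 4.43e-07 and adjusted p = 0.197 with an estimated correlation). Cell cycle genes were lower in monocytes in 29 of 37 (29 adjusted over the list alone, camera adjusted p = 1.07e-09 and adjusted p = 0.291 with an estimated correlation), with Ccna2, the cyclin A2 gene, at -6.52 ± 0.80. Erythroid genes were lower in 14 of 19 (15 adjusted over the list alone, camera adjusted p = 1.14e-06 and adjusted p = 0.386 with an estimated correlation). Heme synthesis genes were lower in 4 of 9 (5 adjusted over the list alone, camera adjusted p = 0.0113 and adjusted p = 0.301 with an estimated correlation). Slc4a1, the red cell anion exchanger gene, had a difference of -8.24 ± 0.52. Immediate early and heat shock genes were higher in monocytes in 10 of 13 (10 adjusted over the list alone, camera adjusted p = 1.69e-06 and adjusted p = 0.184 with an estimated correlation). Their mean level was 12.55 in monocyte array 1 and 10.93 in array 2, and that of the LPS and NF-kB response list 11.78 and 9.65. LPS and NF-kB response genes were higher in 5 of 12 (6 adjusted over the list alone, camera adjusted p = 1.73e-05 and adjusted p = 0.214 with an estimated correlation), and interferon response genes in 5 of 21 against 1 lower (5 adjusted over the list alone, camera adjusted p = 0.00118 and adjusted p = 0.333 with an estimated correlation). Monocyte and macrophage genes were higher in 4 of 20 and lower in 3 (4 adjusted over the list alone, camera adjusted p = 0.025 and adjusted p = 0.513 with an estimated correlation). Klf4 (3.62 ± 0.66) was higher and F13a1 (-3.91 ± 0.64) lower. Mature neutrophil genes did not pass as a list (camera adjusted p = 0.0774), with 2 of 13 higher in monocytes (2 adjusted over the list alone), Il1b (4.34 ± 0.63) and Csf3r (2.24 ± 0.39). Of the called genes 28.7% were higher in monocytes with the deposited values and 57.3% after median centring, where the median of all genes moved from -0.13 to 0.36. The count was 1496 with array weights and 411 in a fit of the pair alone.

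Lymphoid types (NK, B and 4 T cell groups) were set against the myeloid pair, and 3450 genes were higher in lymphoid and 2002 in myeloid cells. Gpr174 (8.93 ± 0.18, adjusted p = 1.29e-13), Jakmip1 (8.30 ± 0.40), Gimap7, a GTPase of the lymphocyte GIMAP family (8.07 ± 0.27), Rras2 (7.72 ± 0.27) and Ifng, the interferon gamma gene (7.64 ± 0.54), were higher on the lymphoid side. S100a9 (-12.47 ± 0.92, adjusted p = 3.28e-08), the siderophore-binding protein gene Lcn2 (-12.18 ± 0.73), Mmp9, a gelatinase gene (-12.06 ± 0.37), Slfn4 (-11.78 ± 0.70) and S100a8 (-11.73 ± 0.96) were higher on the myeloid side, and Hp, Gda, Clec4d, Ceacam10 and Ngp lay between -11.73 and -10.96. T cell genes were higher in lymphoid cells in 20 of 20 (20 adjusted over the list alone, camera adjusted p = 1.34e-07 and adjusted p = 0.119 with an estimated correlation). Ribosome biogenesis genes were higher in lymphoid cells in 18 of 20 (18 adjusted over the list alone, camera adjusted p = 1.84e-05 and adjusted p = 0.184 with an estimated correlation). B cell genes were higher in 11 of 22 and lower in 2 (11 adjusted over the list alone, camera adjusted p = 0.127). Mature neutrophil genes were higher in myeloid cells in 13 of 13 (13 adjusted over the list alone, camera adjusted p = 2.68e-09 and adjusted p = 0.184 with an estimated correlation). So were secondary and tertiary granule genes in 11 of 11 (11 adjusted over the list alone, camera adjusted p = 4.65e-09 and adjusted p = 0.184 with an estimated correlation). Monocyte and macrophage genes were higher in myeloid cells in 14 of 20 (14 adjusted over the list alone, camera adjusted p = 5.36e-05 and adjusted p = 0.301 with an estimated correlation). Interferon response genes followed in 14 of 21 (14 adjusted over the list alone, camera adjusted p = 3.90e-04 and adjusted p = 0.31 with an estimated correlation). Genes of eosinophils, basophils and mast cells were higher in myeloid cells in 4 of 5 tested members (4 adjusted over the list alone, camera adjusted p = 0.00945 and adjusted p = 0.228 with an estimated correlation), led by Siglecf (-6.17 ± 0.16). Of that list 10 genes had a probe set. The share of called genes on the lymphoid side was 63.3% with the deposited values and 44.1% after median centring, which moved the median of all genes from 0.36 to -0.28.

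**Figure D5:**
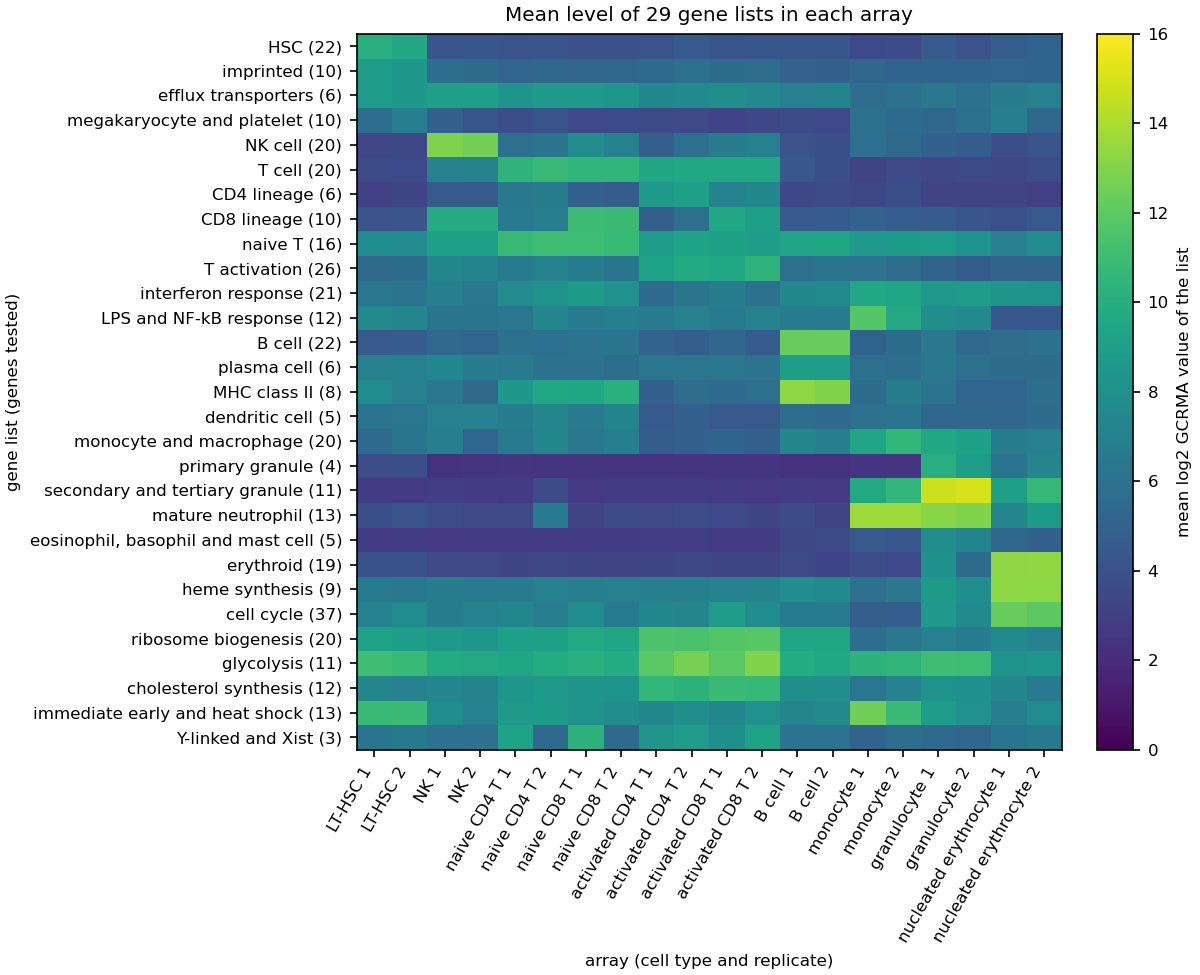
Mean level of each of the 29 gene lists (vertical axis) in each of the 20 arrays (horizontal axis), as a colour scale. Erythroid and heme synthesis genes stand out in the nucleated erythrocyte arrays and B cell genes in the B cell arrays.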

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

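The tests of the Y-linked signal were chosen after that signal had been seen, whereas the test of the difference between the activation effects was planned.

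The effect of activation differed between CD8 and CD4 T cells for 65 genes, by a test of the difference itself, and 10 of the largest on each side among genes whose arrays did not overlap are given here as the CD8 effect minus the CD4 effect. Higher in CD8 were the effects on the chemokine genes Ccl4 (5.40 ± 0.60) and Xcl1 (3.97 ± 0.40), and on Tspan4 (5.22 ± 0.45). Genes that fell in CD4 and fell less or did not fall in CD8 came out on the same side: the sialyltransferase gene St8sia6 (5.08 ± 0.85), Ggt5 (4.86 ± 0.66), Pdlim4 (4.48 ± 0.36), the lectin-like receptor gene Klrd1 (4.29 ± 0.78), Zbtb16 (3.93 ± 0.72), Pik3ap1 (3.85 ± 0.68) and Tox2 (3.83 ± 0.66). Lower in CD8 were the effects on Baiap3 (-6.86 ± 0.68), Tlr3 (-5.28 ± 0.37), Slc6a19 (-5.14 ± 0.26), Itgae (-5.03 ± 0.88), Lcn4 (-4.87 ± 0.29), Olfm1 (-4.44 ± 0.36), Cxxc5 (-3.94 ± 0.41), Ifitm10 (-3.86 ± 0.56), Rcn3 (-3.78 ± 0.41) and Actn2 (-3.60 ± 0.47). Low levels limit the reading of 32 of the 65 genes: 19 fell in CD8 and lay under a log2 value of 5 in naive and activated CD4 T cells, where little fall could be measured, and 13 fell in CD4 and were as low in CD8. Among the named genes these were Baiap3, Tlr3, Slc6a19, Lcn4, Olfm1, Cxxc5, Ifitm10, Rcn3 and Actn2 on the CD8 side and St8sia6, Ggt5, Pdlim4 and Zbtb16 on the CD4 side. The call of Klrd1 was lost under 8 other settings, and those of Pik3ap1 and Zbtb16 under 6 each. Itgae began at 5.28 in naive CD4 T cells, so its fall there was limited too. No technical explanation of these differences was tested.

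Among probe sets that the platform table does not list, 421 met the fingerprint rule of a cell type, 154 of them in nucleated erythrocytes and 126 in LT-HSC, and 52 probe sets listed for several genes met it as well. Their genes were not named. Uty, a Y-linked demethylase gene that did not pass the filter for testing, was above a log2 value of 5 on 3 arrays, at 8.44 in naive CD4 array 1, 6.12 in activated CD8 array 1 and 5.19 in naive CD8 array 1. These values come from 1 of its 4 probe sets, singled out after its values were seen.

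Y-linked transcripts in female samples were weighed as a pattern. Both Eif2s3y and Kdm5d, each read from 1 probe set, lay above a log2 value of 5 in 6 arrays, which argues against cross-hybridisation of a single probe set. The remaining probe sets of these genes were under 5 in all arrays, so each gene rests on 1 of them. Of the 6 arrays 2 hold naive cells, which argues against activation of the T cells as the whole reason. Cells of male mice in these samples are a candidate explanation: 5 of the 6 arrays had less Xist than the lowest of the other arrays, but naive CD8 array 1 had 9.88 against 9.50 in monocyte array 1. A dimmer Xist probe set was under 5 in these 6 arrays and in 4 without the Y-linked signal. The brightest Xist probe set still read 8.14 in activated CD4 array 2, 8.99 in activated CD8 array 2 and 9.88 in naive CD8 array 1. As Xist is an RNA of female cells, this argues against male cells alone in these arrays. For the rest of the 6, male cells alone, a mixture of male and female cells and less Xist in T cells as such cannot be told apart by Xist. A mixture and less Xist in T cells cannot be told apart by Xist in any of the 6. Less Xist by itself would not account for the Eif2s3y and Kdm5d signal. Apart from activation and cells of male mice no biological explanation was tested, and the labels give a single sex.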

How the results depend on the processing

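Settings added after seeing the data were the probe set with the highest group mean, leaving out the naive T cell arrays numbered 2 or 1, and leaving out the granulocyte group; the others were planned. The named calls counted here are the 218 of leading fingerprint genes and of the largest differences in the contrasts. Genes named only as list members, as checks of the labels or as further fingerprint genes were not followed singly. None of the 218 reversed its sign in the fits in which it was tested, and no called gene list did in the settings run for lists. Lists were not rerun without single arrays, naive arrays or granulocytes, or in fits of only the groups compared. Median centring turned which side held more of the called genes: from 28.0% to 51.5% higher in CD4 than CD8, from 28.7% to 57.3% in monocytes than granulocytes, from 63.3% to 44.1% in lymphoid than myeloid cells, from 48.3% to 50.8% in NK than naive T cells, and from 45.1% to 54.0% and 47.9% to 52.8% up on activation of CD4 and CD8. Of 218 named calls of a gene, those kept were 211 without a filter, 217 after quantile normalization, 214 after median centring, 218 with a trended and robust prior, 213 with array weights and 218 with the probe set of highest group mean. With the stricter filter 202 of 203 were kept, with the mean of all probe sets 203 of 210, in fits of only the groups compared 135 of 198, and 2444 of 2560 over the fits without 1 array. Calls lost most often were those of Tox2 (24 settings), Matn2 (23), Il4 (21) and Il17rb (20) in the fingerprints of single CD4 groups. Of 78 gene list results 63 lost their call with an estimated correlation, and the other 15 include lists called under neither setting. With fry 70 were on the same side, 4 lost and 4 gained a call.

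Without a filter the activated CD8 fingerprint held 26 genes, and arrays of a type correlated by at least 0.968. The stricter filter, which tests fewer genes, gave 229 in LT-HSC, 1 in naive CD4, 7 in naive CD8, 2 in activated CD4 and 3 in activated CD8 T cells. Median centring gave 5 in activated CD8 T cells and 306 in monocytes. The mean of all probe sets gave 208 genes between CD4 and CD8. Array weights gave 3 in naive CD4 T cells, 77 in monocytes and 1496 genes between monocytes and granulocytes. The cause was not tested for these. Taking every probe set on its own counts probe sets in place of genes: fingerprints of 710 in LT-HSC, 181 in NK, 12 in naive CD4, 21 in naive CD8, 34 in activated CD8, 243 in B cells, 246 in monocytes, 339 in granulocytes, 1379 in erythrocytes and 634 shared by activated T cells, and contrasts of 7201 for LT-HSC, 5638 and 5321 for activation of CD4 and CD8, 3313 for NK against naive T cells, 3892 for monocytes against granulocytes and 9749 for lymphoid against myeloid cells.

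Fits of only the groups compared leave fewer degrees of freedom and take the spread from those groups alone. In them limma called fingerprints of 121 genes in LT-HSC, 26 in NK, 3 in B cells, 6 in granulocytes and 281 in erythrocytes. It called 0 in naive CD4 (49 at an unadjusted p under 0.05), 0 in naive CD8 (79), 0 in activated CD4 (71), 0 in activated CD8 (351) and 0 in monocytes (340), and 0 shared by all T cells (70), 0 by naive (85) and 0 by activated T cells (911). The contrasts held 22 genes for the difference between activation effects, 140 for CD4 against CD8 and 411 for monocytes against granulocytes. Gene list tests passed 8 times with an estimated correlation and 315 times with fry, in place of 207. Without the naive arrays numbered 2 activated CD8 T cells had 9 genes and activated T cells shared 182. Without those numbered 1 the counts were 9 and 192, and 183 for CD4 against CD8. Without the granulocyte group monocytes had 568, since genes that the myeloid types share then count for monocytes.

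Leaving out 1 array, where the lone array is assumed to vary like the other groups, gave fingerprints of 286 to 368 in LT-HSC, 80 to 116 in NK, 3 to 9 in naive CD4, 10 to 16 in naive CD8, 2 to 7 in activated CD4, 7 to 18 in activated CD8, 95 to 136 in B cells, 90 to 145 in monocytes, 130 to 223 in granulocytes, 610 to 738 in erythrocytes, 9 to 15 shared by T cells, 15 to 24 by naive T cells and 165 to 383 by activated T cells. Contrasts gave 3320 to 3979 for LT-HSC, 2369 to 2843 for activation of CD4, 2135 to 2498 for activation of CD8, 53 to 82 for their difference, 218 to 467 for CD4 against CD8, 1083 to 1690 for NK against naive T cells, 1636 to 2882 for monocytes against granulocytes and 5373 to 5461 for lymphoid against myeloid cells. Counts moved by over 1.5 times in these cases. Naive CD4 had 3 without either array of LT-HSC, NK, B cells, granulocytes or erythrocytes, without naive CD8 array 1 or without activated CD8 array 1. Activated CD4 had 3 without its array 1 and 2 without its array 2. Activated CD8 had 7 without its array 2, 9 without B cell array 2, 8 without granulocyte array 1, 8 without granulocyte array 2 and 8 without erythrocyte array 2. Activated T cells shared 215 without naive CD8 array 1, 211 without naive CD8 array 2 and 165 without activated CD4 array 1. NK against naive T cells gave 1083 without NK array 1.

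Replicate numbers did not pair the arrays in general: over 45 pairs of cell types, the differences between arrays 1 and 2 correlated across genes between -0.26 and 0.21, with 9 above 0.1. Of the pairs of T cell types, activated CD4 and CD8 (0.21), naive and activated CD8 (0.16) and naive CD4 and CD8 (0.12) were above 0.1, so a shared feature of their numbers is not excluded. With the replicate number as a block the LT-HSC fingerprint held 359 genes, the activation contrasts 3228 in CD4 and 2915 in CD8, CD4 against CD8 312, and 217 of 218 named calls were kept. On arrays the signal over background sets a limit: 8383 of 18193 genes did not reach a log2 value of 5 on 2 arrays and were not tested.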

Other observations

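The tests of erythroid and MHC class II transcripts below were chosen after these had been seen, as was 1 test of CD4 against CD8 splits, whereas the tests of neighbouring genes and of the other splits were planned. Of the listed genes of eosinophils, basophils and mast cells 10 had a probe set and 5 passed the filter. Ccr3, Cpa3, Fcer1a, Ms4a2, Tpsb2 and Prss34 were not tested. Granulocyte arrays carried some transcripts of granulocytes other than neutrophils. Genes of eosinophils, basophils and mast cells were higher in them than in the mean of the other types in 4 of 5 tested members (4 adjusted over the list alone, camera adjusted p = 0.00199 and adjusted p = 0.184 with an estimated correlation): Epx, the eosinophil peroxidase gene (7.24 ± 0.24), Prg2, which encodes major basic protein (5.51 ± 0.25), the basophil protease gene Mcpt8 (4.50 ± 0.27) and Siglecf (4.16 ± 0.21). Nucleated erythrocyte arrays held secondary and tertiary granule transcripts, higher than in the mean of the other types in 9 of 11 (9 adjusted over the list alone, camera adjusted p = 1.38e-05 and adjusted p = 0.249 with an estimated correlation), with Ngp at 9.11 ± 0.40 and Ltf, the lactoferrin gene, at 8.23 ± 0.34. A probe set listed for several beta-globin genes read 15.74 and 15.83 in erythrocytes, 14.88 and 14.75 in granulocytes and 12.03 and 12.20 in B cells. In naive T cells it differed between replicates, with 2.34 and 11.99 in the CD4 arrays and 2.41 and 9.35 in the CD8 arrays. The activated arrays read 2.38 and 2.39 in CD4 and 2.37 and 2.29 in CD8.

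Further fingerprint genes, chosen after their values were seen, add to the picture of single cell types. In LT-HSC, Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, had a margin of 7.08, and Slc18a2, a vesicular monoamine transporter gene, 7.43. In NK cells Cma1, a chymase gene, had 6.79 and the chemerin receptor gene Cmklr1 6.22. B cells had Cr2, the complement receptor gene, at 7.82 and Cxcr5, the follicle-homing receptor gene, at 6.33. Nucleated erythrocytes had the blood group genes Kel at 9.05 and Rhd at 8.36 and the water channel gene Aqp1 at 8.01. Activated T cells shared Myc at 3.27 and the spermidine synthase gene Srm at 3.21.

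Fingerprint genes were neighbours more often than random gene sets of the same size in 3 of the 13 fingerprints. Neighbours here are consecutive genes in chromosome order among the 9793 tested genes with a position, so untested genes may lie between them. Only pairs whose symbols differ in their first letters were counted. LT-HSC had 25 such pairs where random sets averaged 12.6 (adjusted p = 0.00325), B cells 6 against 1.51 (adjusted p = 0.0169) and nucleated erythrocytes 101 against 50.3 (adjusted p = 0.0013). The p-values rest on 10000 random sets, and 1e-04 is the smallest unadjusted value they can give. With pairs that share their first letters included the count was 7 of 13. The letter rule kept some related pairs, such as the immunoglobulin pair Igk and Igkv15-103 in B cells. No count without such pairs was made. That neighbouring genes share a fingerprint may reflect shared regulation of a region, and the random sets were not matched on expression.

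Erythroid and cell cycle transcripts in the granulocyte arrays were weighed as a pattern. Both granulocyte arrays had 8 of 19 tested erythroid genes at least 1 above the highest other non-erythroid type, with array 1 at a mean list level of 8.02 and array 2 at 5.64. Erythroid cells in the granulocyte samples cannot be told apart from erythroid transcription in them by this count, and as the only source of the cell cycle transcripts they stay open too, since the arrays disagree. The median cell cycle share of the erythrocyte level was 3.21% in array 1, under the upper quartile of the erythroid genes (5.29%), and 1.13% in array 2, above that quartile (0.793%). All 4 tested primary granule genes, Mpo, Prtn3, Ctsg and Ms4a3, were higher in granulocytes than in erythrocytes and in monocytes, so that cycling granulocyte precursors in the sort remain a candidate explanation. No biological explanation beyond these was tested.

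MHC class II transcripts in the naive T cell arrays were weighed as well. Their median share of the B cell level was at least 3.68% in each of the 4 naive arrays, while the upper quartile of the B cell genes lay between 0.801% and 1.49%, which argues against B cells in the naive T cell samples as the whole source. Of the 8 tested genes 7 lay above both monocyte arrays in all 4 naive arrays, which argues against monocytes. Dendritic cells that culture removes stay open: the dendritic cell list had a median difference of -2.06 on CD4 activation, and that of the MHC class II list was -3.65. A decrease of MHC class II expression within the T cells cannot be told apart from this, as 5 tested dendritic cell genes are few and Ccr9 is expressed by naive T cells too. Of the 9 listed dendritic cell genes 8 had a probe set, and Siglech, Xcr1, Clec9a and Cd209a were not tested. Those of them with a probe set did not pass the filter in the naive T cell or any other arrays.

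Other assignments of the arrays were tried for the comparisons with at least 3 arrays a side. For the shared fingerprints of all T cells (13 genes), of naive T cells (20) and of activated T cells (324), 1 of 100, the real one, gave as many genes and the highest other was 0. Mixing cell types within a group leaves no shared fingerprint whatever the real sets are, so these assignments say nothing about chance. For lymphoid against myeloid cells 1 of 100 gave as many as 5452, with 2176 as the highest other. Mixed groups inflate the spread there too, so this does not exclude chance either. For CD4 against CD8 T cells 5 of 100 gave as many as 321, with 3543 as the highest other, so chance was not excluded over all of them. The others as large put 3 or 4 activated arrays on 1 side, which points to the structure of the samples. When arrays were exchanged only within the naive and within the activated cells, a test added after these counts were seen, 1 of 18 splits gave as many (321, highest other 79), too few splits for a share under 0.05.

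With whole cell types regrouped, 2 of 100 sets of 4 types shared as many genes as the T cells (13, highest other 19, from LT-HSC, monocytes, granulocytes and erythrocytes), 2 of 45 pairs as many as the activated T cells (324, highest other 378, from monocytes and granulocytes), and 1 of 28 splits as many as lymphoid against myeloid (5452, highest other 4771). For the naive pair 5 of 45 pairs shared as many (20, highest other 378). These sets are other groupings of real cell types, so the shares rank real groupings and do not exclude chance.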
